A study of Drosophila melanogaster with 36 samples.

How the data were processed

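Small RNA was sequenced from whole heads of female w1118 flies, with 400 heads per sample, at an age of 5 days (young) or 55 days (old). Heads were collected at 6 zeitgeber times (ZT) that lie 4 h apart, from ZT0 to ZT20, with 3 replicates at each, which makes 36 libraries in 12 groups. The labels describe TRIzol extraction, DNase treatment and Illumina TruSeq libraries with an oligonucleotide that blocks the 30 nt 2S ribosomal RNA fragment. They list Bowtie and the BDGP6 and dm6 builds, without versions. They state no collection date, sequencing batch or light schedule. The 6 libraries that share an age and a replicate number are called a series below, and there are 6 series, 3 per age.

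All 24 deposited tables were used, and every column of values belonged to a listed sample. The deposited miRNA tables hold expected counts per mature miRNA arm, that is, counts with fractions where a read fits several places. The deposited piRNA tables also hold expected counts, per numbered cluster. The authors gave both kinds of table as RPM too, that is, as reads scaled to a library total. The miRNA RPM equals the count divided by the miRNA total of the library, whereas the piRNA RPM divides by a larger total of 36.5 to 91.6 M reads that the files do not name. The file names call the values adjusted without a definition. The miRNA tables list 673 features, of which 495 carry a miRBase name and 178 an identifier that begins with rr, whose meaning the files do not give. The piRNA tables list 56 clusters in a pair of column sets, here called the first and the second set, and nothing in the files says what tells the sets apart or where a cluster lies. In the first set 10 clusters, and in the second set 1 cluster, had a count of 0 in every library.

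Counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Features were kept with filterByExpr over the 12 groups, which left 363 miRNA and 85 piRNA features, and libraries were scaled with TMM factors over their own table. Levels are CPM, counts relative to the library size on this scale, given as the mean ± SD over the libraries of an age or group. The age effect was the old minus young coefficient of a quasi-likelihood fit with time point as a factor. Rhythms were tested with a cosine and a sine term of 24 h period in each age, and their difference between the ages with the corresponding interaction terms. A further test asked of each miRNA whether the age difference depended on the time point as a factor. Adjusted p-values are Benjamini-Hochberg values over all tested features of a table, with a threshold of 0.05. Rhythm sizes are fitted peak-to-trough differences on the log2 scale. Composition measures were compared with 2-sided permutation tests of 100000 resamples over libraries, and with exact permutation tests over the means of 3 young and 3 old series, where 0.1 is the smallest p possible. These and other listed choices were made before the data were examined.

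The miRNA lists, 18 in number and fixed with those choices, are the mature arms of the let-7 complex, the cluster of miR-34, miR-277 and miR-317, that of miR-283, miR-304 and miR-12, the miR-310 and the miR-959 to miR-964 clusters, and the K box, miR-9/79 and miR-92/310 seed families, with both arms of each hairpin whether or not an arm carries the seed. Further lists hold miRNAs linked to ageing and neuroprotection, clock and rest-activity, neurons, eye and sense organs, muscle, fat body and metabolism, and immune regulation. The last 3 hold miRNAs of other tissues, namely ovary, testis and early embryo. The lists with at least 3 tested arms, 17 in number, were tested with limma 3.58.1 camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Features to be named were set by rule. They were the 12 largest rises and the 12 largest falls with age (piRNA 5 and 5) among called features with a mean of at least 10 CPM and a single direction of the difference at all 6 time points. In each age they also included the 10 most significant rhythms (piRNA 4) with a mean of at least 10 CPM or, where no rhythm passed, the 3 smallest p, and the 5 smallest p of each test of a difference. Fixed miRNAs were always reported, as were up to 4 members of each list. Features whose library values correlate above 0.999 and whose totals differ by less than 2.0% were treated as near-identical copies.

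Hairpin positions come from the gene annotation on BDGP6. Of 296 miRBase-named arms tested, 294 matched a hairpin by name, and 185 hairpins were placed, of which 73 lie in an intron, 59 overlap an exon and 53 lie outside genes on their own strand. The miR-263a hairpin was not matched, so no position is given for it.

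Alternatives were RLE factors, library totals alone, no filter, a filter at a mean of 10 CPM, DESeq2 1.42.0, limma on log2(RPM + 1), a replicate block, limma-voom with a correlation within series (statmod 1.5.0), time point as a factor, a series block, counts summed per series, miRNA library sizes for piRNA, and leaving out each library or series in turn. Others were chosen after seeing the data: leaving out libraries rich in ovary miRNAs or in miR-184-3p, the level of ovary miRNAs as a covariate, scaling to the total behind the piRNA RPM, leaving out the rr features, their copies apart from the others, each library left out for the composition measures, and summing the 2 piRNA column sets. Counts were also simulated, drawn independently for each library from the feature means, dispersions and library sizes of the data. They hold no correlation within a series and no library that stands apart, so their rates may not carry over to the data. Changes of 0.5, 1 and 2 on the log2 scale were recovered for the miRNA age effect in 86.6%, 97.0% and 100% of cases with 5 false calls among 194. For a young miRNA rhythm they were recovered in 35.8%, 70.1% and 95.5%. A rhythm difference between the ages was recovered in 19.4%, 55.2% and 77.3%, and a young piRNA rhythm in 0%, 0% and 50%. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the plots.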

Results

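The series measured small RNAs in fly heads around the day at both ages, which puts 3 questions to the tables: what differs between young and old heads, what follows a daily rhythm, and whether the rhythm differs between the ages. Each of the 12 groups had 3 libraries. Total miRNA counts per library ranged from 16.2 to 30.4 M and total piRNA counts from 139322 to 441447. The most abundant miRNAs were miR-8-3p, which acts in the fat body and in growth control (167316 ± 20810.2 CPM in young and 181918 ± 22243 in old heads, n = 18 each), and miR-184-3p, known from female germline development (159938 ± 160094 and 118501 ± 100388 CPM). All 36 pairs of replicates differed by more than counting error, with a chi-square per degree of freedom of at least 152.61, and correlated across miRNAs with r from 0.974 to 0.997. Nothing in the labels says whether replicates came from separate cohorts, so the p-values measure only the spread between these samples.

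Some libraries stood apart from their group. The ovary miRNA miR-318-3p, which acts in follicle cells, reached 460 CPM in young ZT4 replicate 3, 784 CPM in young ZT8 replicate 3 and 563 CPM in old ZT0 replicate 1, against a median of 17.4 CPM in 15 young and 13.5 CPM in 15 old libraries without such an excess. Counts in the second piRNA column set were 14051, 13548 and 11526 in these 3 libraries and had a median of 2372 in those 15 young ones. Lesser excesses of the ovary list, 2.88, 3.82 and 3.26 times the median of the age, were found in young ZT8 replicate 1, old ZT20 replicate 1 and old ZT0 replicate 2. Members of the list disagreed there: miR-989-3p stood at 7.30 CPM in the first and at 0.406 and 0.513 in the old pair, near the old median of 0.497, and old ZT0 replicate 2 also had no excess of miR-956-3p (218 CPM) or of second-set counts (2759). Separately, miR-184-3p made up 45.3% of the miRNA counts in young ZT0 replicate 1 and 37.1% in old ZT0 replicate 3.

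**Figure D1:**
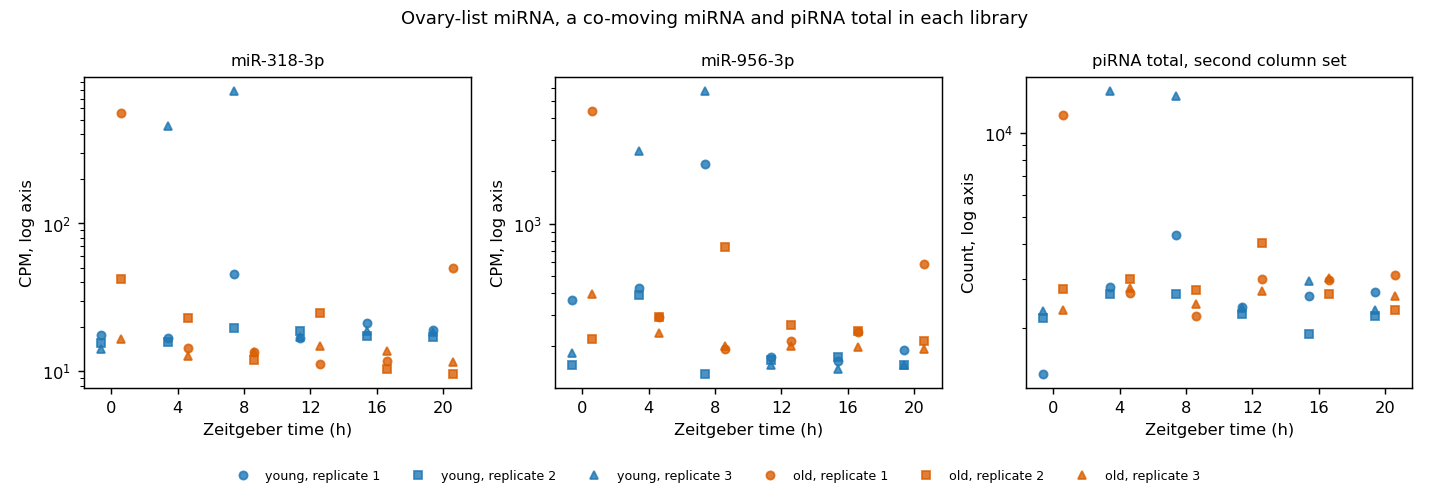
CPM of miR-318-3p and of miR-956-3p and the count total of the second piRNA column set against zeitgeber time in hours, on logarithmic axes, with 1 point for each of the 36 libraries. In 3 libraries miR-318-3p stands at 460, 784 and 563 CPM, and the second-set total at 14051, 13548 and 11526.

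Between young and old heads, miR-308-3p, an intronic miRNA of the ribosomal protein gene RpS23 (chromosome 2R, 14215802 to 14215864, minus strand), rose from 65.5 ± 13.8 to 187 ± 31.6 CPM (n = 18 per age, log2 change 1.51, SE 0.096, adjusted p = 1.55e-15). Its other arm miR-308-5p rose by 0.85 on the log2 scale, a call that ended under scaling to the RPM total, and miR-13b-2-5p, from an intron of the chaperonin gene CCT2 (chromosome X, 9091230 to 9091299, plus strand), from 14.3 ± 1.82 to 32.2 ± 3.96 CPM. The deepest falls among features of at least 10 CPM were those of miR-2c-5p, from 127 ± 14.9 to 31.6 ± 4.75 CPM (log2 -2.01, chromosome 3R, 15417744 to 15417845, minus strand, in an exon of lncRNA:CR45911), and of miR-193-5p, from 955 ± 112 to 264 ± 32.6 CPM (log2 -1.86, chromosome 3L, 21574014 to 21574121, plus strand, outside genes). The abundant miR-957-3p (chromosome 3L, 22518196 to 22518291, minus strand, outside genes) fell from 29952 ± 2772 to 15668 ± 1376 CPM, a log2 change of -0.94 (SE 0.048).

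Falls of similar size were measured for miR-990-5p, in an intron of CG8910 (-1.24), for miR-375-3p, a conserved miRNA first known from pancreatic islet cells (-1.04, from 256 ± 36.5 to 125 ± 18.4 CPM), and for miR-993-3p (-0.99). Lower levels in old heads were also found for miR-998-5p, in an intron of the cell cycle gene E2f1 (-0.86), miR-4940-5p, in the 3' untranslated region of the synaptic gene nwk (-0.79), and miR-2b-1-5p, in that of the kinase gene Btk (-0.77). The same held for miR-1010-5p (-0.79), miR-1012-3p (-0.75) and miR-1017-3p (-0.78), which lie in introns of SKIP, Lerp and the acetylcholine receptor gene nAChRalpha2. Among the rr features, rr794157-1a-3p-miR rose from 9.17 ± 1.64 to 69.6 ± 13.8 CPM (2.93), rr767199-3a-5p-miR by 1.77 and rr527087-1a-5p-miR by 1.19. A further 6 of the largest rises (rr884543-1b-5p-miR, rr817686-1b-5p-miR, rr817650-3a-5p-miR, rr817694-3b-5p-miR, rr817655-5b-5p-miR and rr817690-5b-5p-miR) are near-identical copies, each at 174 ± 69.5 CPM in young and 697 ± 179.6 in old heads. Which of the 6 loci gave these counts is uncertain. By the naming rule, which admits no others, each feature of this and the preceding paragraph differed in the same direction at 6 of 6 time points.

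The abundant miRNAs chosen in advance moved less. Young and old levels were 60643 ± 3964 and 41393 ± 3232 CPM for miR-276a-3p, a regulator of timeless and of dopamine receptor signalling (log2 -0.55), and 29179 ± 3052 and 20241 ± 2067 CPM for miR-277-3p, which controls branched-chain amino acid breakdown (-0.53). The growth regulator bantam-3p fell by 0.32 on the log2 scale (adjusted p = 3.42e-04), miR-279-3p, which acts on JAK/STAT signalling in rest-activity output, by 0.49, and miR-125-5p, made with let-7, by 0.59. The neuronal miR-124-3p rose by 0.41 (adjusted p = 1.21e-04), or stood at -0.22 under scaling to the RPM total. Smaller falls were those of let-7-5p, a developmental timing miRNA (-0.22, SE 0.076, adjusted p = 0.0140), and of miR-34-5p, whose loss shortens fly life (-0.24, SE 0.089, adjusted p = 0.0184). No call was made for miR-263a-5p and miR-263b-5p, which protect sense organ cells from death (log2 0.39 and -0.35, adjusted p = 0.0724 and 0.118), or for miR-100-5p (0.08, adjusted p = 0.476). The calls of let-7-5p and miR-34-5p ended with library totals alone, without a filter, at 10 CPM, with limma on log2(RPM + 1), with limma-voom, without rr features and with counts summed per series, and that of bantam-3p with library totals alone and with limma on log2(RPM + 1). Without young ZT0 replicate 1 the call of let-7-5p ended (-0.15, adjusted p = 0.0622) and one began for miR-263a-5p (0.54, adjusted p = 0.00963), and without old ZT0 replicate 3 one began for miR-263b-5p (-0.43, adjusted p = 0.0337).

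By edgeR 221 of 363 miRNA features differed between the ages, 104 higher and 117 lower in old heads. These were 71 higher and 107 lower of the 296 miRBase-named features, and 33 higher and 10 lower of the 67 rr features. Counted once per set of near-identical copies, 195 of 335 features differed (89 higher, 106 lower). Changes over 2-fold numbered 45, of which 30 were rises. Among the calls, 50 rises and 59 falls had a mean over 10 CPM and a single direction at all 6 time points. The split between rises and falls depended on the scaling. Library totals alone gave 145 higher and 72 lower with a shift of the median of all features to 0.19 on the log2 scale, limma on log2(RPM + 1) gave 147 and 70, and scaling to the total behind the piRNA RPM gave 28 and 251 with the median at -0.62. Directions are therefore relative to the typical miRNA. Without the 3 ovary-rich libraries 228 features differed, and without these and the 2 rich in miR-184-3p 245 did.

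**Figure D2:**
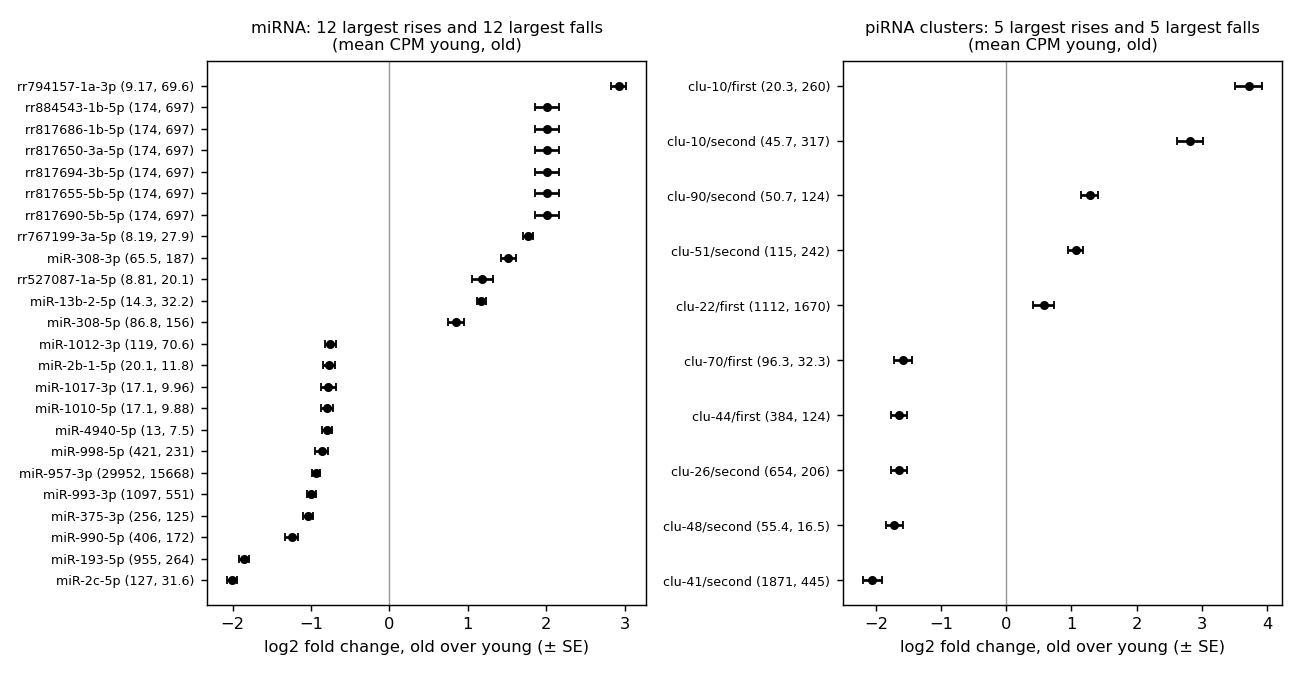
Log2 change from young to old heads for the 12 largest rises and falls of miRNA features and the 5 largest of piRNA features that meet the naming rule, with the mean CPM in young and old heads (n = 18 each) beside each name and bars for the standard error. Of the miRBase-named features drawn, miR-308-3p at 1.51 rose most and miR-2c-5p at -2.01 fell most, on the TMM scale.

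Members of the lists fixed in advance moved as follows. For the miR-34, miR-277 and miR-317 cluster, which holds ageing-related miRNAs in lncRNA:CR43459 and beside it on chromosome 3R, 4 of 6 arms fell and none rose, with miR-34-3p at -0.68 and miR-277-5p at -0.54 on the log2 scale. In the neuron list 8 of 16 arms fell, among them miR-133-5p (-0.70), miR-932-3p, from an intron of the neuroligin gene Nlg2 (-0.67), miR-219-3p (-0.65) and miR-190-5p (-0.49), and 1 rose, miR-124-3p, which reached -0.22 under scaling to the RPM total. For the miR-283, miR-304 and miR-12 cluster, in introns of the Golgi protein gene Gmap on chromosome X, 5 of 6 arms rose, with miR-12-5p at 0.45, miR-12-3p at 0.66, miR-283-3p at 0.48 and miR-304-3p at 0.22. Under scaling to the RPM total, miR-12-5p, miR-283-3p and miR-304-3p turned negative (-0.16, -0.11 and -0.40) and the call of miR-12-3p ended. With counts summed per series the calls of miR-283-3p and miR-304-3p ended, and that of miR-304-3p also with limma-voom and without the 6 libraries with any ovary excess.

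Arms of the let-7 complex, which lie in lncRNA:let7C, went both ways, with 2 of 6 rising (let-7-3p at 0.76, a call that ended under scaling to the RPM total, and miR-100-3p at 0.41 but -0.20 under that scaling) and 2 falling (let-7-5p and miR-125-5p). The ageing and neuroprotection list had 5 rises and 10 falls among 22 arms, and the clock and rest-activity list 8 rises and 13 falls among 27, including miR-276b-3p (-0.56) and miR-375-3p. All 4 arms of the feeding-related miR-959 to miR-964 cluster fell, but from levels under 1 CPM, with miR-959-3p at -2.12, miR-960-5p at -1.01, miR-961-5p at -0.80 and miR-964-5p at -1.03. Among hairpins of the K box family, whose 3p arms repress proapoptotic genes, 12 of 23 arms rose and 9 fell, with miR-2a-2-5p at 0.61 (-0.0048 under scaling to the RPM total) beside the miR-308, miR-13b-2 and miR-2c arms named above. The count includes 5p arms, which lack the seed of the family, and copies of 1 sequence listed at several loci.

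The miR-9/79 family, which includes the sense organ regulator miR-9a, had 2 rises (miR-9a-5p at 0.69, a call that ended under scaling to the RPM total, and miR-9b-5p at 0.43 but -0.18 under that scaling) and 1 fall (miR-9c-5p at -0.24, a call that ended with library totals alone, limma on log2(RPM + 1) and counts summed per series) among 10 arms, with miR-9a-3p at 0.26 not called. In the eye and sense organ list 4 of 11 arms rose, among them miR-263a-3p (0.52) and miR-996-5p (0.29), which turned to -0.11 and -0.33 under scaling to the RPM total. The 3 falls there included the photoreceptor miRNA miR-210-3p (-0.33), whose call ended with library totals alone and with limma on log2(RPM + 1). The fat body and metabolism list had 3 rises and 5 falls among 14 arms, with miR-33-5p, from an intron of the lipid regulator gene SREBP, at 0.45, or -0.17 under scaling to the RPM total. Its median was 0.01, its mean -0.13 and its test pointed down, while the eye list had a median of -0.01, a mean of 0.03 and a test pointing up. Immune regulation had 3 rises and 3 falls among 18 arms. Both the miR-310 cluster (8 arms) and the miR-92/310 seed family (10 arms) had 2 rises and no fall, from miR-312-5p (1.16) and miR-310-3p (0.92), with miR-311-5p (0.56), miR-991-3p (0.13) and miR-92b-3p (0.17) not called. Both rises lost their call under scaling to the RPM total, and miR-310-3p also with counts summed per series. The only muscle arm, miR-1-3p, was at 0.09 and not called. Leaving out 1 library ended the call of miR-304-3p (0.20 without young ZT20 replicate 1) and began one for miR-1-3p (0.40 without young ZT0 replicate 1), miR-311-5p (0.90 without young ZT8 replicate 3) and miR-994-3p (-2.47 without old ZT0 replicate 1). For miR-9a-3p, at adjusted p = 0.0545, leaving out any of 10 libraries began one.

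For other tissues, none of 4 ovary arms was called (miR-318-3p at -0.77, miR-989-3p at -0.64, miR-994-5p at -0.52 and miR-994-3p at -0.99), values that hang on single libraries. Without young ZT4 replicate 3, young ZT8 replicate 3 and old ZT0 replicate 1 in turn, miR-318-3p was at -0.10, -0.29 and -1.09, miR-989-3p at 0.53, -0.24 and -1.52, and miR-994-5p at 0.51, 0.20 and -1.02. Without the 6 libraries with any excess, miR-318-3p was called at -0.37 and miR-989-3p at 0.97. Meanwhile 4 of 12 testis arms rose and 1 fell, with miR-984-3p at 1.82, miR-303-3p at 1.39 and miR-984-5p at 0.74, all under 1 CPM. The fourth, miR-982-5p, was at 0.27, or -0.35 under scaling to the RPM total, which also ended the call of miR-984-5p. In the early embryo list 4 of 8 arms rose and 1 fell, with miR-5-5p at 0.65 and miR-6-3p at 0.70, whose 3 copies make up the other rises. These rises lost their call under scaling to the RPM total, and the miR-6-3p copies also with counts summed per series. Counts adjusted over the list alone equalled those over all features in each of the 18 lists. In limma camera, 0 of 17 lists passed after adjustment, with 3 at an unadjusted p under 0.05, namely the miR-34, miR-277 and miR-317 cluster, the neuron list and the miR-283, miR-304 and miR-12 cluster, each at adjusted p = 0.248. An estimated correlation gave 0 lists, at adjusted p = 0.546 for the first of these and for the neuron list and 0.597 for the last. By fry, which asks whether members move 1 way on balance without comparison to other miRNAs, 12 lists passed.

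Relative to miRNAs, piRNA cluster reads were higher in old heads, at 14.8 ± 3.11 per 1000 miRNA reads against 9.07 ± 1.35 in young heads (SD, n = 18 each, 1.62-fold). Old ZT8 replicate 1 stood apart at 25.5, and without it the old mean was 14.2 ± 1.66 and the log2 difference 0.65. Cluster piRNAs, known for silencing transposons, made up 0.380% ± 0.0597 of the total behind the RPM values in old and 0.409% ± 0.0340 in young heads. The share of miRNAs in that total was 25.9% ± 2.03 in old and 45.5% ± 3.02 in young heads. Features with rr identifiers took 0.476% ± 0.103 of miRNA counts in old and 0.112% ± 0.0237 in young heads (4.25-fold). Most of this was the 6 near-identical copies named above, at 0.445% ± 0.103 in old and 0.0949% ± 0.0239 in young heads, while the other rr features took 0.0311% ± 0.00274 and 0.0169% ± 0.00110 (1.83-fold). The log2 differences were 0.70 for the piRNA to miRNA ratio, -0.82 for the miRNA share and 2.09 for the rr share, each with p = 1e-05, the smallest that 100000 permutations can give (adjusted p = 1.5e-05 over 6 measures). The piRNA share differed by -0.12 on the log2 scale (permutation p = 0.033, adjusted p = 0.033), or by -0.15 without old ZT8 replicate 1 (permutation p = 4.1e-04). Without young ZT12 replicate 1, young ZT8 replicate 3 or any 1 library of old replicate 3 its permutation p lay just above the threshold, between 0.0502 and 0.0632. Over series means (3 against 3) the exact permutation p was 0.1, the smallest possible, for the first 3 measures and 0.4 for the piRNA share.

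**Figure D3:**
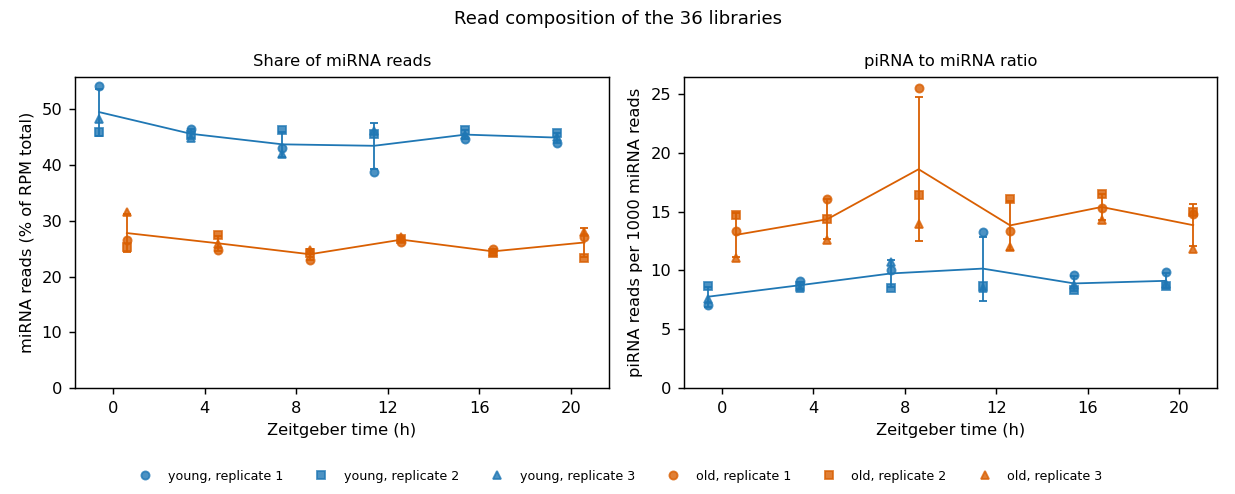
Share of miRNA reads in the RPM total and piRNA reads per 1000 miRNA reads against zeitgeber time in hours, with a point per library and the mean ± SD of 3, for young and old heads. The piRNA reads per 1000 miRNA reads average 9.07 in young and 14.8 in old heads.

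A change of the age difference over the day was sought next. The smallest p belonged to miR-306-5p, in an intron of the checkpoint kinase gene grp (chromosome 2L, 16698404 to 16698488, plus strand), which stood at 1307 ± 174 CPM in young and 1009 ± 224 in old heads at ZT0 and at 929 ± 139 and 1711 ± 378 CPM at ZT16 (n = 3 each). Its adjusted p in edgeR was 0.171, and so were those of the ovary miRNAs miR-994-5p and miR-318-3p and of miR-958-3p, with miR-989-3p at 0.192. The count was 0 of 363 by edgeR, with 24 at an unadjusted p under 0.05, 7 by DESeq2 and 0 by limma. It was 1 without young ZT4 replicate 2 and 5 without young ZT8 replicate 2. The latter fit leaves young ZT8 replicates 1 and 3, both with an ovary excess. Calls that began there include those of miR-994-5p, miR-318-3p, miR-989-3p and miR-958-3p.

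Around the day in young heads, miR-263a-3p, the lesser arm of a miRNA that protects sense organ cells, went from 32.0 ± 13.8 CPM at ZT0 to 62.6 ± 5.56 at ZT12 (n = 3 each), with a fitted peak at ZT12.5 and a peak-to-trough size of 0.93 on the log2 scale (adjusted p = 0.0142). In old heads it went from 46.7 ± 17.9 to 81.8 ± 13.4 CPM, with a size of 0.70, a peak at ZT11.8 and an adjusted p of 0.206. The low at ZT0 is partly that of the libraries rich in miR-184-3p, young ZT0 replicate 1 at 16.6 and old ZT0 replicate 3 at 26.3 CPM, without which the young call had an adjusted p of 0.0152 (0.0474 without the young one alone). That call ended with library totals alone, limma on log2(RPM + 1), time point as a factor, the ovary covariate and scaling to the RPM total, and without the 6 libraries with any ovary excess. The arm miR-275-5p (chromosome 2L, 7425795 to 7425892, plus strand, in lncRNA:CR43857) went from 107 ± 31.3 at ZT0 to 175 ± 19.4 CPM at ZT8 in young heads (size 0.59, adjusted p = 0.0314). The largest fitted rhythms among called features of at least 10 CPM were those of miR-318-3p (chromosome 3R, 10408302 to 10408369, plus strand; size 4.16, adjusted p = 0.0309), of miR-956-3p (chromosome 3L, 11773731 to 11773878, minus strand; 4.06, adjusted p = 0.00926) and, at 1.90, of miR-312-3p (adjusted p = 0.0264). These 3 peaked near ZT6, between the groups that hold young ZT4 replicate 3 and young ZT8 replicate 3, where miR-956-3p stood at 2606 and 5715 CPM, with 2194 CPM in young ZT8 replicate 1, against a median of 167 in the 15 young libraries without an ovary excess.

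By edgeR 16 of 363 miRNA features passed in young heads, with 36 at an unadjusted p under 0.05. The 3 smallest p in old heads were those of miR-964-5p, miR-1007-5p and miR-4919-3p, each at an adjusted p of 0.167. There the count was 0, with 42 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma. Without the 3 ovary-rich libraries 4 features passed in young heads (miR-9378-5p, miR-263a-3p, miR-989-3p and miR-956-3p, where miR-9378-5p and miR-989-3p are named after their values were seen), and without the 6 libraries with any excess 0 did. Leaving out young ZT8 replicate 3 alone gave 0, and leaving out young ZT16 replicate 2, ZT20 replicate 2, ZT4 replicate 3 or ZT16 replicate 3 gave 10 each. The calls of miR-263a-3p and miR-956-3p ended without young ZT8 replicate 3 (adjusted p = 0.0547 and 0.0631), those of miR-312-3p and miR-318-3p without any of those 5, and that of miR-275-5p without any of 31 libraries. The call of miR-318-3p also ended with the replicate block and the series block, those of miR-318-3p, miR-312-3p and miR-956-3p with limma on log2(RPM + 1), limma-voom and the ovary covariate, that of miR-312-3p with time point as a factor, and that of miR-275-5p with RLE factors, at 10 CPM, with time point as a factor and with the ovary covariate. No member of the let-7 complex, the clusters of miR-34, of miR-12 and of miR-959, or the ageing, neuron, fat body, K box and testis lists passed in young heads. Adjusted over the list alone and over all features in young heads, 4 and 3 ovary arms passed, 6 and 3 of immune regulation, 4 and 1 of the miR-310 cluster, 5 and 2 of its seed family, 2 and 1 of the early embryo list, 1 and 0 of muscle, 2 and 2 of clock and rest-activity, 1 and 1 of eye, and 1 and 1 of miR-9/79. In old heads, where 0 passed over all features, 4 ovary, 2 let-7 complex, 2 immune, 1 clock and 1 miR-959 to miR-964 arm passed over the list alone. The ovary list stood at 45.4 times the median of the age in old ZT0 replicate 1, with lesser excesses in old ZT0 replicate 2 and old ZT20 replicate 1. Whether the 4 ovary arms pass without these libraries was not tested.

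**Figure D4:**
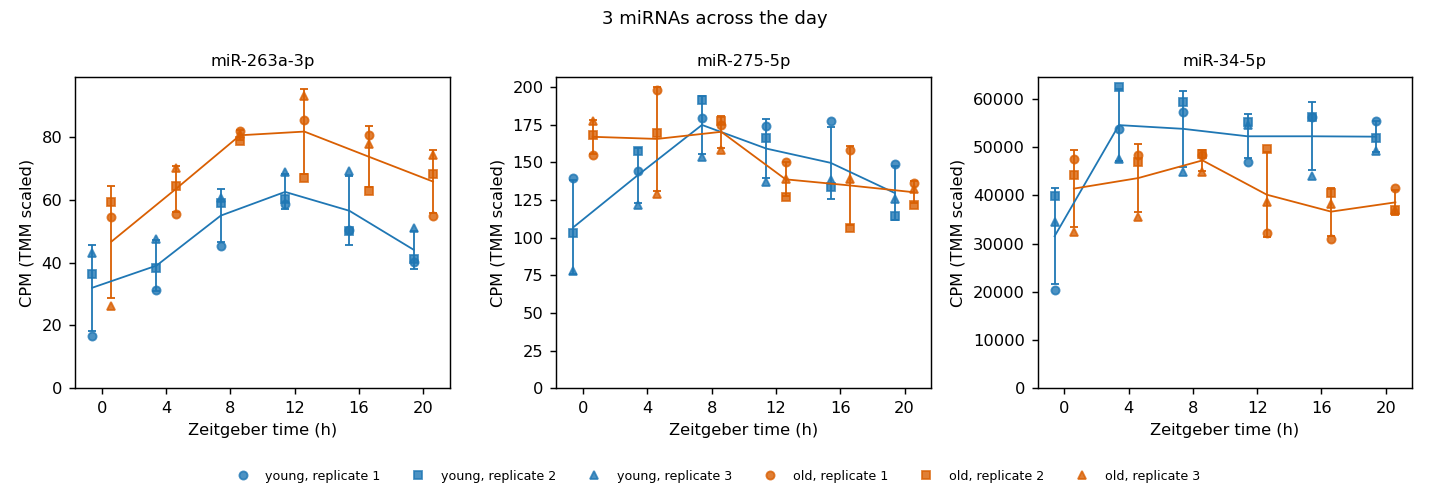
Levels of miR-263a-3p, miR-275-5p and miR-34-5p in CPM against zeitgeber time in hours, for young and old heads, with each library as a point and the mean ± SD of 3. The mean of miR-263a-3p is lowest at ZT0 and highest at ZT12 in both ages, with the lowest points, at 16.6 and 26.3 CPM, in the 2 libraries rich in miR-184-3p.

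The rhythm itself differed between the ages for miR-4-3p, of the early embryo cluster, at an adjusted p of 0.0497 and a level of 0.521 CPM. Its young level was 0.935 ± 0.478 CPM at ZT4 and 0.323 ± 0.0636 at ZT16, and its old level 0.347 ± 0.158 and 0.918 ± 0.791 (n = 3 each, edgeR). This was the only call among 363, with 33 at an unadjusted p under 0.05, and 4 by DESeq2, and it ended with limma on log2(RPM + 1), limma-voom, the ovary covariate and without rr features. The next smallest p, miR-958-3p, miR-314-5p, miR-958-5p and miR-989-3p, reached an adjusted p of 0.0934. For miR-263a-3p the difference between the ages was 0.28 on the log2 scale (adjusted p = 0.9995 in edgeR). Leaving out any 1 of 19 libraries gave a count of 0, and so did leaving out the 3 ovary-rich libraries. Leaving out young ZT8 replicate 2, so that replicates 1 and 3 with their ovary excess remain, gave 6. These include miR-958-3p, miR-314-5p, miR-958-5p and miR-989-3p.

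Among piRNA clusters, clu-10 rose most with age, from 20.3 ± 11.4 to 259.6 ± 48.5 CPM in the first column set (n = 18 per age, log2 3.72, SE 0.21, adjusted p = 1.98e-16) and by 2.82 in the second. In the second set clu-41 fell from 1871 ± 507 to 445 ± 70.5 CPM (-2.05), and clu-48 and clu-26 fell by 1.72 and 1.65 on the log2 scale. First-set counts of clu-44 and clu-70 changed by -1.64 and -1.59. Rises were also found for clu-90 (1.28) and clu-51 (1.06) in the second set and for clu-22 in the first (0.58, adjusted p = 0.00670). In total 23 of 85 features from 18 clusters differed by edgeR, 10 higher and 13 lower. The ovary-rich libraries moved this count to 30 when the 3 were left out, and to 38 without the 6. Scaling by the miRNA table gave 39, of which 33 were higher, and summing counts per series gave 8, without clu-22, clu-90 and clu-51.

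Most called rhythms of piRNA clusters in young heads had a fitted peak near ZT6, with clu-53 in the second set at 298 ± 292 CPM at ZT8 and 39.0 ± 7.59 at ZT16 (n = 3 each, adjusted p = 0.00342, edgeR). Similar fitted peaks were found for clu-29 and clu-17 in the second set and for clu-46 in the first, each at adjusted p = 0.00832. These 4 calls ended with limma on log2(RPM + 1), limma-voom and the ovary covariate, and that of clu-29 also with DESeq2. At ZT8 the SD of clu-53 was near its mean, and that group holds the ovary-rich young ZT8 replicate 3. Without that library the calls of clu-29, clu-17 and clu-46 ended (adjusted p = 0.0714, 0.0698 and 0.0698). In young heads 39 of 85 features from 29 clusters passed, and in old heads 0 did, with 10 at an unadjusted p under 0.05 and 0 by DESeq2 and limma. Old heads had the smallest p for clu-41, clu-38 and clu-46 in the first set, each at an adjusted p of 0.188. The difference between the ages passed for 1 feature, clu-29 in the second set (adjusted p = 0.0465), with 26 at an unadjusted p under 0.05 and 0 by DESeq2. That call also ended with limma on log2(RPM + 1), limma-voom, the replicate block, RLE factors, no filter, at 10 CPM, the ovary covariate, scaling to the RPM total, without the 2 libraries rich in miR-184-3p and in 31 of 36 fits that left out 1 library. The next 4 were clu-46, clu-16 and clu-41 in the first set and clu-53 in the second, at adjusted p from 0.0799 to 0.0839. Without the 3 ovary-rich libraries the young count was 2 (clu-41 in the first set and clu-53 in the second) and the difference count 0, and without young ZT8 replicate 3 alone the young count was 1. Leaving out young ZT4 replicate 3, ZT20 replicate 1 or ZT20 replicate 3 gave young counts of 8, 21 and 23.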

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

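Tests chosen only after the result was seen were those of ovary RNA, of time of day and of 1 abundant miRNA for miR-184-3p, of the 5 libraries for the age effect, and the shuffled reference for peak times.

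Rhythms that differed between the ages by the interaction test itself numbered 2. The miRNA miR-4-3p had an adjusted p of 0.0497 at 0.521 CPM, and clu-29 in the second piRNA set had 0.0465. In 15 of 100 splits that shuffled ages within time points as many miRNA rhythm differences were called, up to 150, so chance cannot be excluded for the miRNA count of 1, and splits with many more calls point to structure among the libraries. For the piRNA count of 1, 3 of 100 splits gave as many (highest other 1), but DESeq2 and limma gave 0.

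Young rhythm calls were made for 16 miRNA and 39 piRNA features. Shuffling time points among young libraries gave as many in 2 of 100 splits for miRNAs (highest other 33) and in 2 of 100 for piRNAs (highest other 47). In each case 1 other split called more than the real one, which points to structure among the libraries, so chance is not excluded. Without young ZT8 replicate 3 alone the counts were 0 and 1. RNA of ovary in 3 libraries may account for the piRNA calls: 2 of 39 were still made without these libraries against 39 of 39 without 3 other libraries of the same groups, and the ovary miRNAs miR-318-3p and miR-989-3p reached 784 and 33.6 CPM, though miR-318-3p is also found in the other libraries at a median of 17.4 CPM in young heads. First-set totals had no such excess in these 3 libraries (217758, 213642 and 268853). Their medians were 227724 in young and 295253 in old libraries without an ovary excess. Both sets shared 1 scaling, with TMM factors of 3.20, 2.71 and 2.40 there, which lowers features that did not rise. First-set clu-40, for example, had fitted peaks at ZT18.5, ZT18.5 and ZT19.1 in the 3 young series. Some calls may thus reflect the scaling. The filter was applied anew in each refit, and a feature that it dropped counted as not called. For miRNAs 4 of 16 calls were still made, against 14 without the 3 other libraries. Fewer libraries alone do not explain this drop. As 4 lies at the bound of this test and not below it, the test cannot tell ovary RNA and a rhythm apart. Of the 4, miR-989-3p is on the ovary list. It and miR-956-3p stood at 7.30 and 2194 CPM in young ZT8 replicate 1, which was kept. Their medians were 0.242 and 167 in the 15 young libraries without an excess. Without the 6 libraries with any ovary excess no miRNA call was left. Fitted peaks of the 3 young series within 4 h of each other for 10 of 16 miRNAs (62.5%, against 20.8% of calls in 99 shuffles) are consistent with a shared rhythm, though several lie near ZT6, where an ovary excess in 2 of the 3 series would align them too, while 14 of 39 piRNAs (35.9% against 18.3%) leave it open.

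High miR-184-3p in young ZT0 replicate 1 and old ZT0 replicate 3 came with other miRNAs more than 2-fold from their group mates in the same direction in both libraries, 17 of 167 with miR-184-3p itself and 16 without, against 0 in each of 4 other ZT0 pairs. Among them miR-10-5p, miR-263a-5p (2.26 and 2.20 on the log2 scale), miR-278-5p and miR-998-3p were higher and miR-932-5p, miR-996-3p and miR-263a-3p (-1.25 and -1.11) lower. That count argues against 1 abundant miRNA taking more of the reads. Time of day as the cause is argued against by 0 of 4 other ZT0 libraries above every library of the other time points. More transcription of hairpins, or RNA of other cells that shifts both arms alike, is argued against by the opposite shifts of the 2 arms of miR-263a. The same holds for the lack of a shared deviation of both arms over 97 hairpins (r = -0.156 and -0.117, Spearman's rho -0.146 and -0.052). In the ovary-rich libraries r was 0.74 to 0.87 but rho only 0.187 to 0.383, and hairpins are not independent replicates. RNA of cells with another ratio of the arms is not excluded, as it need not shift both arms alike. A bias of library preparation between arms and miRNAs stays open and was not tested, as does a biological difference of these samples.

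The age effect on miRNAs, 221 calls, was exceeded or equalled by 1 of 100 splits that shuffled ages within time points, the real one (highest other 74). This argues against a chance arrangement of single libraries only, as it takes the libraries of a series as independent. Without the 5 libraries rich in ovary miRNAs or miR-184-3p 215 of 221 calls were still made in the same direction, and 207 of 221 with every library thinned to 16201304 counts, which argues against those libraries and against depth as the cause of the calls. The lower miRNA share of old libraries cannot be told apart from a gain of some miRNAs, since 48 of 104 rises became negative when scaled to the total behind the RPM values, while 28 features were still called higher. The labels give no batch of preparation, so one that followed age could not be told apart from age. Library totals did differ between the ages, with 79.8 M behind the RPM values in old and 56.7 M in young libraries on average. Whole series shuffled between ages make 10 splits, too few for a share under 0.05, of which 1, the real one, gave as many calls (highest other 32 for miRNA and 1 for piRNA). An effect of age itself stays open as the biological explanation.

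Other counts against splits of the samples were as follows. For the piRNA age effect, 23 calls, 1 of 100 splits of single libraries gave as many, the real one (highest other 21). Libraries of a series may not be independent, and whole series make only 10 splits, so chance is not excluded. For the age by time point test of miRNAs and for old rhythms of miRNAs and piRNAs, each with 0 calls, all 100 splits gave as many, with highest others of 19, 1 and 1.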

How the results depend on the processing

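Chosen after seeing the data were the alternatives on ovary-rich and miR-184-3p-rich libraries, the ovary covariate, the RPM total, the rr features and their copies, the summed column sets and the piRNA share without 1 library. The count of 221 miRNAs with an age effect lay between 174 and 279 except for 123 of 168 with a mean of at least 10 CPM, where fewer features were tested. With the replicate block, replicate number as an additive term as in a paired design, counts were 230 (age, miRNA), 14 (young rhythm), 0 (old rhythm), 1 (difference), 0 (interaction) and 0 lists, and for piRNA 18, 29, 0 and 0. Deviations of same-numbered series of the ages had a mean r of 0.061, 0.022 and 0.082, against -0.108 to 0.035 for differently numbered ones. These values are small and were not tested. Within a series, deviations of the libraries had a mean r of 0.209, 0.072 and 0.241 in young replicates 1, 2 and 3. In old replicates 1, 2 and 3 it was 0.0045, 0.0081 and 0.098. Tests over single libraries take them as independent, so their p-values may be too small.

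The interaction count of 0 became 7 with DESeq2 and 1 without the 6 libraries with any ovary excess. Young miRNA rhythms, 16, became 4 at 10 CPM, 1 with limma on log2(RPM + 1), 2 with limma-voom and correlated series, 9 with time point as a factor, 4 without the 3 ovary-rich libraries, 0 without the 6, 3 without the 5 and 0 with the ovary covariate. The miRNA rhythm difference, 1, became 4 with DESeq2 and 0 at 10 CPM, with limma, limma-voom, without the 3, 6 or 5 libraries, with the covariate and without rr features. The piRNA age count, 23, became 39 with miRNA library sizes, 38 without the 6 libraries, 39 without the 5, 39 with the covariate, 11 with column sets summed and 8 with counts summed per series. Young piRNA rhythms, 39, became 14 with DESeq2, 0 with limma and limma-voom, 16 with time point as a factor, 2 without the 3 libraries, 0 without the 6 or the 5 and with the covariate, and 17 with column sets summed. Old piRNA rhythms, 0, became 3 with time point as a factor. The piRNA rhythm difference, 1, became 17 with library totals alone, 39 with miRNA library sizes, and 0 with RLE factors, no filter, 10 CPM, DESeq2, limma, limma-voom, the replicate block, without the 3, 6, 2 or 5 libraries, with the covariate, the RPM total and column sets summed. Lists past the threshold rose from 0 to 12 with fry, which tests another question. The piRNA to miRNA ratio, a log2 difference of 0.70, had an exact permutation p of 0.1 over series means, the smallest possible for 3 against 3. The cause was not tested except where fewer features or samples, or another null hypothesis, are part of the alternative.

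Leaving out 1 library at a time gave 217 to 230 age calls, 0 to 5 interactions, 0 to 19 young, 0 old and 0 to 6 differing miRNA rhythms, and for piRNA 17 to 32, 1 to 41, 0 and 0 to 10, with the ratio at 0.65 to 0.73. Leaving out 1 series gave 202 to 226, 0 to 1, 0 to 17, 0 to 1 and 0 to 1 for miRNA, 12 to 29, 0 to 41, 0 to 1 and 0 to 15 for piRNA, and 0.63 to 0.81. Young miRNA rhythms fell to 0 without young ZT8 replicate 3 and to 10 without young ZT16 replicate 2, ZT20 replicate 2, ZT4 replicate 3 or ZT16 replicate 3. Young piRNA rhythms fell to 1 without young ZT8 replicate 3, 8 without ZT4 replicate 3, 21 without ZT20 replicate 1 and 23 without ZT20 replicate 3. Interactions rose to 5 without young ZT8 replicate 2 and 1 without young ZT4 replicate 2. Of 36 fits the miRNA rhythm difference was 0 in 19, 6 without young ZT8 replicate 2 and 2 without young ZT20 replicate 2, old ZT8 replicate 2 or old ZT4 replicate 3, and the piRNA one was 0 in 31, 3 without young ZT4 replicate 1, 10 without young ZT8 replicate 2 and 5 without young ZT4 replicate 3.

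Under scaling to the RPM total, miR-124-3p (-0.22), miR-100-5p (-0.54), miR-100-3p (-0.20), miR-263a-3p (-0.11), miR-996-5p (-0.33), miR-1-3p (-0.49), miR-33-5p (-0.17), miR-991-3p (-0.48), miR-2a-2-5p (-0.0048), miR-9b-5p (-0.18), miR-9a-3p (-0.37), miR-92b-3p (-0.44), miR-12-5p (-0.16), miR-283-3p (-0.11), miR-304-3p (-0.40) and miR-982-5p (-0.35) changed sign, along with the shift of the median. Without the 6 libraries miR-989-3p changed sign to 0.97. Among 4542 refits of 79 named age effects of miRNAs, 4414 kept direction and side of the threshold, as did 200 of 295 for 5 young miRNA rhythms and 573 of 580 for 10 piRNA age effects.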

Other observations

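The mirtron list and its test were chosen after the result was seen; the test of both arms was planned.

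Arms of 1 hairpin did not always move together with age: for miR-276a the 3p arm was at -0.55 and the 5p arm at 0.68 on the log2 scale, though the 5p arms of miR-276a and miR-276b have identical values and cannot be assigned to 1 of them. For miR-210, expressed in photoreceptors, the 3p arm was at -0.33 and the 5p arm at 0.59, for let-7 the abundant 5p arm at -0.22 and the 3p arm at 0.76, for miR-993 the 3p arm at -0.99 and the 5p arm at 0.15, and for the neuronal miR-124 the 3p arm at 0.41 and the 5p arm at -0.28 (edgeR, n = 18 per age). Of 97 hairpins with both arms tested, 29 had both arms called in the same direction, 10 in opposite directions, miR-276a and miR-276b among them, 37 had 1 arm called and 21 neither. Opposite directions depended on the scaling: under scaling to the RPM total 3 of the 10 had estimates of opposite sign and 0 had both called, with miR-210-5p at -0.03, miR-993-5p at -0.47 and miR-124-3p at -0.22. The ratio of arms changed in 50 hairpins at an adjusted permutation p under 0.05. Scaling cancels in this ratio except through a small constant added to the counts, which matters for arms with few counts. If both arms followed the level of their hairpin, their changes would correlate and their ratio would stay the same. Across hairpins, which are not independent replicates, r was 0.430 and Spearman's rho 0.438, which by itself leaves this open. The changed ratio in 50 of 97 hairpins argues against it for those 50, as far as libraries of a series are independent. Those among them with few counts in an arm are less certain. For the other hairpins it stays open.

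Several mirtrons, miRNAs made from short introns by splicing in place of Drosha, fell with age. Examples are miR-1004-5p, from an intron of CG43707 (91.5 ± 8.19 to 58.5 ± 4.33 CPM, log2 -0.64), miR-1003-3p (-0.83), miR-1009-3p (-0.45) and miR-1008-5p (-0.44), besides miR-1010-5p and miR-1012-3p, whose more abundant partner arms miR-1010-3p and miR-1012-5p were at -0.10 and -0.09 and not called. Of 21 arms of miR-1003 to miR-1016, 10 fell, 1 rose (miR-1007-3p, 0.31) and 10 were not called, with a median of -0.25. Mirtrons as a class may fall relative to other miRNAs: camera with an estimated correlation gave p = 0.00888, a hypothesis that was formed and tested on the same data.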
